A study of Mus musculus with 12 samples.

How the data were processed

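Gene expression was measured with Illumina bead arrays in 12 intestinal samples of Apc-min mice, a strain that forms intestinal adenomas because 1 copy of the tumour suppressor Apc is mutated. Per the labels, total RNA was isolated with Trizol, purified on RNeasy columns and turned into biotin-labelled cRNA. The samples fall into 6 groups of 2 arrays: normal tissue and tumour tissue, each from mice with unaltered Notch signalling (wild type), from mice in which Villin-Cre deletes Mib1 in the gut epithelium (Notch-inactivated), and from mice in which Villin-Cre switches on a Rosa Notch1 transgene (Notch-activated). Mib1 is a ubiquitin ligase that Notch ligands need in order to signal. The labels give the tissue as normal or tumour and do not name the segment of gut. They also do not say whether the 2 arrays of a group came from separate animals. The p-values therefore measure the spread between these samples, which may be technical, and the number of arrays limits their precision.

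The deposited table of the series holds 1 value per probe and array, and its values were used as they stand. They read as log2 signals that the authors quantile normalized: the median was 5.54 and the maximum 14.2 on every array, and the sorted values of the columns differed by at most 5.43e-04. The base of the logarithm and the background correction are not given in the sources used here, so the log2 scale is an inference from the range of values. A companion table with signals and detection p-values was not analysed here, because none of its 24 columns of per-sample values could be tied to a sample. The design written beforehand had assumed such signals, and the deposited normalized values took their place.

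Of 46628 probes, 549 control probes were left out. The background of an array was taken as the 95th percentile of its 51 probes for sequences foreign to the mouse, which lay between 5.58 and 5.82 on the log2 scale. A probe was kept when it exceeded this limit on at least 2 arrays, which left 23814 probes (51.1%). Between 35.1% and 47.4% of probes exceeded the limit on a single array. This share was 35.1% to 41.9% on normal arrays and 42.9% to 47.4% on wild type and Notch-inactivated tumour arrays. On the Notch-activated tumour arrays it was 39.2% and 39.4%, within the range of normal tissue. The limit was lower on wild type and Notch-inactivated tumour arrays (5.58 to 5.64) than on the others (5.66 to 5.82). Whether this bears on the differences between groups was not tested. The transgene reporter probes for eGFP and IRES are foreign sequences too and were read separately.

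The files do not pair probes with gene names. Most probe identifiers hold 1 or 2 leading zeros and then a number, which was read as an NCBI gene number and looked up in a RefSeq gene table of the assembly GRCm38.p6. This reading is an inference, and it was tested. Of the numbers after 1 zero, 81.1% matched a gene, against 19.2% after the numbers had been shifted. For those after 2 zeros the shares were 84.8% and 19.5%. The 57 probes so named as ribosomal protein genes had a median signal of 13.2, and 98.2% of them lay above 8, while 361 probes named as olfactory and vomeronasal receptors had a median of 5.32 with 0% above 8. After 2 zeros, 18 ribosomal protein probes had a median of 6.53 with 44.4% above 8, so names from that class are less firm. Of the 203 genes tabulated, 90 came from it, among them Nkd1, Sox4, Wnt6, Il1rl1, Ptn, Dcn, Lyz2, Bcas1, Slc12a8, Defa25, H2-D1, Krt13, Kcnq1, Shoc2, Mib1 and Apc. Another 9 probes were named through RefSeq accessions. In all, 9805 probes carried 1 of 8106 symbols, and 6008 of them were kept. Where a gene had several kept probes, as 666 genes did, the one with the highest mean over all 12 arrays stood for it. This gave 23071 features, 5265 named genes and 17806 unnamed probes. Alpha-defensins and lysozymes are families of near-identical sequences, so their probes may read more than 1 member.

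Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 6 groups over all 12 arrays, so that all groups shared 1 estimate of the spread (6 residual and 3.77 prior degrees of freedom, typical SD 0.12 on the log2 scale). Adjusted p-values are Benjamini-Hochberg over the 23071 features within each of 12 contrasts, and a feature was called at an adjusted p under 0.05. The contrasts were tumour against normal tissue in each genotype and on average, the genotypes against each other within each tissue, and the tissue difference of each Notch genotype's effect. Fold changes are differences of group means, given with their standard error (SE), and levels are means ± SD of the 2 arrays. A gene is said to have risen or fallen only where it was called. Where a gene lay at background on both arrays of 1 group, the fold is a bound: the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the background limit and the gene's own signal. Differences of 4 or 6 groups were bounded by the same limits, and their direction was taken as left open where a group on the brighter side lay at background.

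Before the data were examined, 30 gene lists were fixed, and the 19 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast. Camera compares a list with all other features. Of 228 such tests, 94 were called, and 3 of these also held with a correlation estimated from the arrays: the enterocyte, myeloid and adenoma lists in the tissue difference of the Notch-activated effect. Genes named in the text were taken by a rule fixed beforehand. It gave the 6 largest rises and 6 largest falls of called genes with a regular symbol and no overlap between the groups, up to 4 members of a called list, up to 2 of another list, and 8 genes of the Notch and Wnt pathways in every sample. Of these 8, Notch1, Hes1, Lgr5 and Axin2 had no probe that could be named.

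The fit was tested on simulated data for Notch-inactivated against wild type tumours with 23071 features. Of 100 features changed by 1 on the log2 scale, 91 were recovered, and of 100 changed by 0.5, 18 were recovered, with 7 false calls among 22714 unchanged features. In the same simulated contrast every list was shifted in turn over 10 draws of noise. A shift of 0.5 was found in 184 of 190 runs, or 157 with an estimated correlation, and a shift of 1 in 190 and 188. The Paneth cell list was the exception, found in 4 of 10 draws at 0.5. Simulated genes vary independently, so these shares say nothing about correlated genes.

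Alternatives were no filter on dim probes, the mean over a gene's probes, eBayes with trend and robust settings, array weights, a replicate block, an added requirement of a doubling or halving, fits to only the groups compared, and leaving out each array in turn. Cyclic loess on the deposited values, a stricter filter, a crossed pairing and list tests without the features left open by background were added after the data had been seen. Of 15 pairs of groups, 2 showed a correlation of same-numbered arrays over 0.1 (range -0.38 to 0.34), so the replicate numbers were not taken to pair samples. The value of -0.38 belonged to wild type and Notch-inactivated tumours, so arrays of unlike number may share a factor there. The main fit did not model such a factor. A few genes that the naming rule selected are not reported here.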

Results

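Expression of 5265 named genes and 17806 unnamed probes was compared across 12 arrays of normal and tumour tissue from Apc-min mice, with 2 arrays for each of 6 groups. The series asks how Notch signalling bears on colorectal tumour progression, so tumours were compared with normal tissue in each genotype, and genotypes with each other in each tissue. Over the features tested, the replicate arrays of a group correlated at r between 0.985 and 0.991. Wild type and Notch-inactivated tumours correlated with each other at r of at least 0.984. Notch-activated tumours lay further from wild type tumours (0.936 to 0.947), and closer to Notch-activated normal tissue (0.954 to 0.964) than wild type tumours lay to wild type normal tissue (0.863 to 0.880). These correlations are across features, which are not independent replicates. Every log2 difference below rests on 2 arrays per group, and its SE comes from the spread shared by all groups. Where a probe lay at background on both arrays of 1 group, only a lower bound of the fold is known, which is written as at least N-fold. A difference built from 4 or 6 groups is given as a bound in the same way, and as left open where a group on its brighter side lay at background.

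The genes altered by the study were examined first. Mib1, the gene deleted in the Notch-inactivated mice, had a log2 signal of 6.40 ± 0.05 in wild type, 6.12 ± 0.07 in Notch-inactivated and 6.51 ± 0.19 in Notch-activated normal tissue (mean ± SD, n = 2). In tumours the Mib1 signals were 6.75 ± 0.03, 6.23 ± 0.06 and 6.82 ± 0.02. Against wild type, the Notch-inactivated Mib1 difference was -0.28 in normal tissue (limma, adjusted p = 0.180) and -0.52 in tumours (adjusted p = 0.153), and neither was called. Against Notch-activated samples Mib1 was lower in Notch-inactivated tumours, by a log2 difference of 0.59 (adjusted p = 0.00269). In normal tissue that Mib1 difference was 0.39 (adjusted p = 0.0428), a call lost in 11 of the 12 fits that left out 1 array, with adjusted p between 0.0548 and 0.196, and with cyclic loess (0.35, adjusted p = 0.0741). Whether the Mib1 probe lies in the deleted part of the gene is not known, so by itself it checks no label. Apc had a log2 signal between 6.59 and 6.89 in the 6 groups. The probes for Atoh1 (group means 5.25 to 5.51), a regulator of the secretory lineage that Notch represses, and for Myc (5.12 to 5.26) did not pass the background filter. Atoh1 exceeded the limit on 1 array, Notch-inactivated tumour array 1 (5.58).

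The Notch1 transgene was traced through 2 reporter sequences that such alleles carry, eGFP and the internal ribosome entry site (IRES). The eGFP probe read at least 9.50 on each of the 4 arrays labelled Notch-activated and at most 5.48 on the 8 others. For IRES the corresponding values were 7.39 and 5.57. An exact permutation test of 4 arrays against 8 gives p = 0.00202 for eGFP and for IRES (one-sided), the smallest that these arrays allow. The test takes the arrays as separate samples, which the labels do not state, and the p-value would be larger if they are not. The eGFP and IRES probes lay at background in wild type samples, and the Notch-activated mean exceeded wild type at least 18.6-fold for eGFP and 5.71-fold for IRES in normal tissue, and at least 15.9-fold and 3.78-fold in tumours. The probes for Cre (group means 5.17 to 5.33) and for another GFP sequence (5.28 to 5.58) lay at background in every group. A further control probe for Cre read 8.26, 7.61 and 8.30 in wild type, Notch-inactivated and Notch-activated normal tissue and 5.35, 5.91 and 7.51 in tumours. Another read 6.26, 5.88 and 6.38 in normal tissue and 5.27, 5.45 and 5.87 in tumours. The eGFP and IRES probes trace the transgene and do not measure the activity of the pathway. In the list of Notch pathway genes and targets 5 genes were measured: Lfng, Nrp1, Rbpj, Mib1 and Dll4. In Notch-activated against wild type tumours 0 of them rose and 2 fell. The list was not called there (camera without the features that background leaves open, adjusted p = 0.254).

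**Figure D1:**
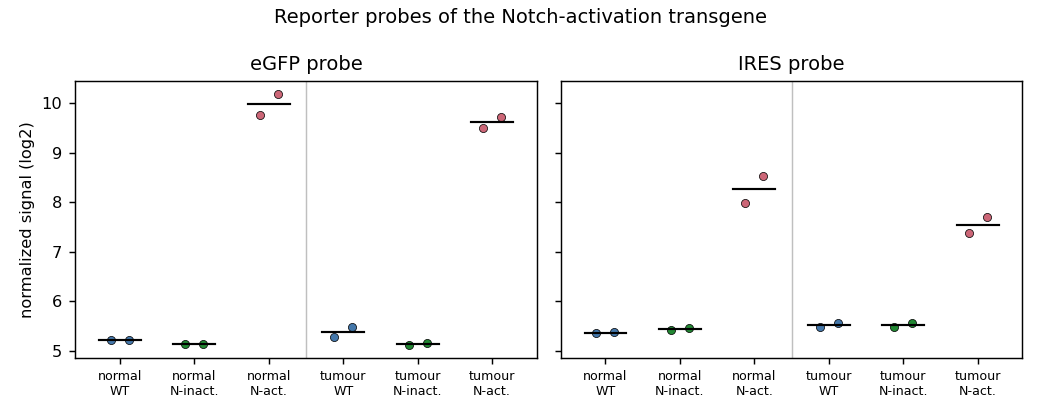
Normalized log2 signal of the eGFP and IRES probes on each array (points, 2 per group) with the group mean (bar), for normal and tumour tissue of the 3 genotypes. The 4 Notch-activated arrays read at least 9.50 for eGFP and 7.39 for IRES, above all 8 other arrays.

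In wild type mice, tumours differed from normal tissue by a rise of Wnt target, Paneth cell, stromal and myeloid genes and a fall of goblet cell, enterocyte and colonic genes. Il1rl1, the receptor of interleukin 33, rose at least 86.5-fold, Igfbp5, a binding protein of insulin-like growth factors, at least 84.7-fold, and the growth factor Ptn at least 46.6-fold. With the mean over its probes the log2 rise of Il1rl1 was 3.41, and it was 3.05 in Notch-inactivated and 2.56 in Notch-activated mice and 3.01 on average. Igkc, the constant part of the immunoglobulin kappa chain, rose by 5.89 (SE 0.54). Among the steepest falls were those of Mptx1, a mucosal pentraxin (-5.37, SE 1.08), Selenbp1 (-4.65, SE 0.27), Gsdmc3 (-4.29), Gsdmc2 (-4.26), the butyrate transporter Slc5a8 (-4.03) and the sodium-proton exchanger Slc9a2 (-3.80). Of the Wnt targets, 9 of 10 measured genes rose and 0 fell (also 9 when adjusted over the list alone). Nkd1, a feedback inhibitor of Wnt signalling, rose at least 17.6-fold, the transcription factors Prox1 and Sox4 by 3.79 (SE 0.14) and 3.14 (SE 0.21), and the ligand Wnt6 at least 2.96-fold. Camera gave the Wnt list an adjusted p = 1.12e-05, with adjusted p = 0.0525 with an estimated correlation. The list of genes known to be raised in mouse colorectal adenoma, which shares Nkd1, Prox1, Wnt6, Cd44 and Cldn2 with the Wnt list, gained 8 of 9 members, among them Igfbp4 (5.33, SE 0.18), with adjusted p = 1.37e-06, and adjusted p = 0.0525 with an estimated correlation.

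Paneth cells, which secrete antimicrobial peptides and are otherwise a small intestinal cell type, were represented by 10 genes, of which 8 rose and 1 (Mptx1) fell in wild type tumours. The alpha-defensin Defa5 rose at least 63.3-fold, Defa21 at least 16.6-fold and Habp2 at least 8.86-fold, and the lysozyme Lyz1 rose by 5.76 (SE 0.51). Camera gave adjusted p = 9.93e-04, and adjusted p = 0.204 with an estimated correlation. Goblet cell genes fell in 5 of 8 cases (8 adjusted over the list alone), with Bcas1 at -3.07 (SE 0.34), Slc12a8 at -2.43 (SE 0.24) and the mucin Muc4 at -2.12 (SE 0.22). The goblet list had adjusted p = 6.29e-04, and adjusted p = 0.204 with an estimated correlation. Enterocyte genes fell in 8 of 9 cases, such as the brush border protease Mep1b (-2.66), the glucose transporter Slc5a1 (-2.46) and the peptide transporter Slc15a1 (-1.24), each with an SE of at most 0.19. Of the colonic markers 9 of 11 fell, with Car1 at -2.73 (SE 0.40) and Mettl7b at -3.45 (SE 0.38). These lists had adjusted p = 1.69e-04 and 6.29e-04, and adjusted p = 0.0525 and 0.0851 with an estimated correlation.

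Markers of other cell types moved with the wild type tumours as well. All 9 myeloid genes rose: Lyz2, the lysozyme of macrophages and neutrophils, by 4.56 (SE 0.22), the chemokine Cxcl2 at least 21.7-fold, and the complement genes C1qb and C1qa at least 8.57-fold and 3.76-fold. Of 8 fibroblast and matrix genes 7 rose, with Mgp at least 41.1-fold, Dcn by 4.89 (SE 0.37), Col3a1 at least 6.70-fold and Col1a1 at least 5.08-fold. All 5 endothelial genes rose, among them Emcn at least 6.73-fold and Robo4 at least 4.03-fold. The adjusted p of the myeloid, fibroblast and endothelial lists was 9.06e-07, 7.57e-06 and 1.02e-04, and their adjusted p with an estimated correlation was 0.0525, 0.0851 and 0.171. Haemoglobin transcripts were higher too, Hba-a1 by 3.53 (SE 0.65). Cholesterol synthesis genes fell in 8 of 11 cases (Hmgcs1 -1.23) and interferon response genes in 7 of 10 (Oas1a -3.06, or -1.97 with the mean over its probes, and Irf7 -2.80). Those 2 lists had adjusted p = 6.09e-04 and 0.0182, and adjusted p = 0.204 and 0.317 with an estimated correlation. Of 15 proliferation genes 6 rose, such as Mcm7 (1.14, SE 0.18), with adjusted p = 0.0306, and adjusted p = 0.592 with an estimated correlation. Regenerative and fetal-like genes rose in 4 of 6 cases (adjusted p = 0.0197, and adjusted p = 0.204 with an estimated correlation). The median, mean and test of the stem cell list differed in sign (0.08, -0.41 and up, adjusted p = 0.888), as did those of the tuft cell list (0.11, -0.14 and up, adjusted p = 0.765). In all, 5422 features were called higher and 5901 lower in wild type tumours, 49.1% of those tested, among them 1311 and 1358 named genes. With cyclic loess the balance turned, to 6104 higher and 4853 lower. The Gsdmc2 call ended without wild type tumour array 1 (-3.12, adjusted p = 0.0526).

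Notch-inactivated tumours also differed from their own normal tissue by higher Wnt target, myeloid and stromal genes and lower goblet and enterocyte genes, while the Paneth list was not called. Il1rl1 rose at least 59.2-fold, Ptn at least 52.0-fold, Mgp at least 56.4-fold and the protease inhibitor Serpina3n at least 41.3-fold, while Igfbp5 rose by 5.84 (SE 0.21) and the metallothionein Mt4 by 5.18 (SE 0.38). Among the steepest falls were those of Aqp4, a water channel (-4.25, SE 0.52), Slc5a8 (-4.14), Fa2h (-4.02), Mettl7b (-3.97) and Sycn (-3.90), and Car1 had -3.69. Of the 10 Wnt targets 9 rose, Nkd1 at least 20.7-fold, Prox1 by 3.50, Sox4 by 3.13 and Wnt6 at least 3.78-fold (adjusted p = 2.07e-05, and adjusted p = 0.0731 with an estimated correlation). Of the Paneth genes 1 rose and 1, Mptx1 (-4.20), fell, with a list adjusted p of 0.676. The Mptx1 call ended without Notch-inactivated normal array 1 (-2.81, adjusted p = 0.0773) or tumour array 2 (-2.83, adjusted p = 0.0793). Myeloid genes rose in 8 of 9 cases (Lyz2 4.46, C1qb 3.37) and fibroblast genes in 8 of 8 (Col3a1 at least 6.06-fold), with adjusted p = 4.16e-06 and 2.79e-05, and adjusted p = 0.0731 and 0.113 with an estimated correlation. Goblet genes fell in 5 of 8 cases and enterocyte genes in 7 of 9 (adjusted p = 0.00139 and 7.28e-04, and adjusted p = 0.255 and 0.0776 with an estimated correlation). Glycolysis genes fell in 7 of 13 cases, for example Ldha (-0.55) and Gpi1 (-0.49), with adjusted p = 0.0265, and adjusted p = 0.463 with an estimated correlation.

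Across the 23071 features, the tumour difference in Notch-inactivated mice followed that in wild type mice with r = 0.894 and a slope of 0.83, without shared arrays. In Notch-inactivated mice 5731 features were higher and 5879 lower in tumours. Of these, 4445 were also called higher in wild type (1347 from independent lists of those sizes), 4597 also lower (1504), and 40 were called in opposite directions. Features are not independent, so these values describe the overlap only.

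In Notch-activated mice stromal, endothelial and myeloid genes and 6 of 10 Wnt targets rose in tumours, and no Paneth gene was called. By the test of the difference between genotypes, the tumour change was smaller than in wild type mice for Sox4 (-1.45, SE 0.29, adjusted p = 0.0112), Igfbp4 (-1.42, SE 0.25, adjusted p = 0.00663) and Lyz1 (-4.63, SE 0.72, adjusted p = 0.00377). It was also smaller for the myeloid genes Cxcl1 (-3.72, adjusted p = 0.00346), Lyz2 (-2.11, adjusted p = 0.00316), C1qb (-2.13 or lower) and C1qa (-0.92 or lower). For Nkd1, Prox1, Wnt6 and Defa5 it is left open, because Notch-activated normal tissue lay at background. Il1rl1 rose by 5.22 (SE 0.37), Igfbp5 by 4.78 (SE 0.21), Serpina3n by 4.70 (SE 0.26), the neutrophil gene S100a9 by 4.49 (SE 0.60), Dcn by 4.46 (SE 0.37), and osteopontin (Spp1) at least 21.1-fold. Mgp rose at least 12.3-fold, Col3a1 at least 4.35-fold, Robo4 at least 3.76-fold, Emcn by 2.54 and Lyz2 by 2.45. The fibroblast (7 of 8 rose), endothelial (5 of 5) and myeloid (9 of 9) lists had adjusted p = 2.90e-07, 6.48e-07 and 6.48e-07, and adjusted p = 0.115, 0.132 and 0.0711 with an estimated correlation. Wnt targets rose in 6 of 10 cases (8 adjusted over the list alone), with Sox4 at 1.68, beside 3.14 in wild type mice, Ccnd1 at 1.14, beside 1.17, and Cd44 at 0.94, while Nkd1 rose at least 1.25-fold. The Wnt list had adjusted p = 2.07e-04, and adjusted p = 0.124 with an estimated correlation. Of the 10 Paneth genes 0 rose and 0 fell by limma (0 adjusted over the list alone), with Lyz1 at 1.13 (adjusted p = 0.134) and a list adjusted p of 0.822, at a median of -0.04 and a mean of 0.00. Lyz1 was called when Notch-activated tumour array 1 was left out (2.06, adjusted p = 0.0102). No goblet gene of 8 was called, and the list had adjusted p = 0.506.

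Among the falls in Notch-activated tumours were the sodium-proton exchanger Slc9a3 (-2.56, SE 0.50), Cyp4f14 (-2.28), the mast cell protease Mcpt4 (-1.79), Eno3 (-1.74), the prostaglandin-degrading enzyme Hpgd (-1.63) and Fa2h (-1.53). The Slc9a3 call ended without Notch-activated normal array 2 (-2.09, adjusted p = 0.0565). Cholesterol synthesis genes fell in 8 of 11 cases (Stard4 -0.78; adjusted p = 3.41e-05, and adjusted p = 0.186 with an estimated correlation). Enterocyte genes fell in 4 of 9, including Mep1b (-1.13), with adjusted p = 0.0122, and adjusted p = 0.145 with an estimated correlation. In Notch-activated mice 2802 features were higher and 2952 lower in tumours, 5754 in all, and with cyclic loess 3134 and 2220. Without Notch-activated normal array 2, tumour array 1 or tumour array 2 the count was 2671, 3177 and 2656. At least a doubling or halving was reached by 740 of them, 600 higher and 140 lower, against 3030 in wild type mice. Against the wild type tumour difference, r was 0.744 and the slope 0.41, with 2286 features higher in both (659 from independent lists), 2366 lower in both (755) and 62 called in opposite directions.

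**Figure D2:**
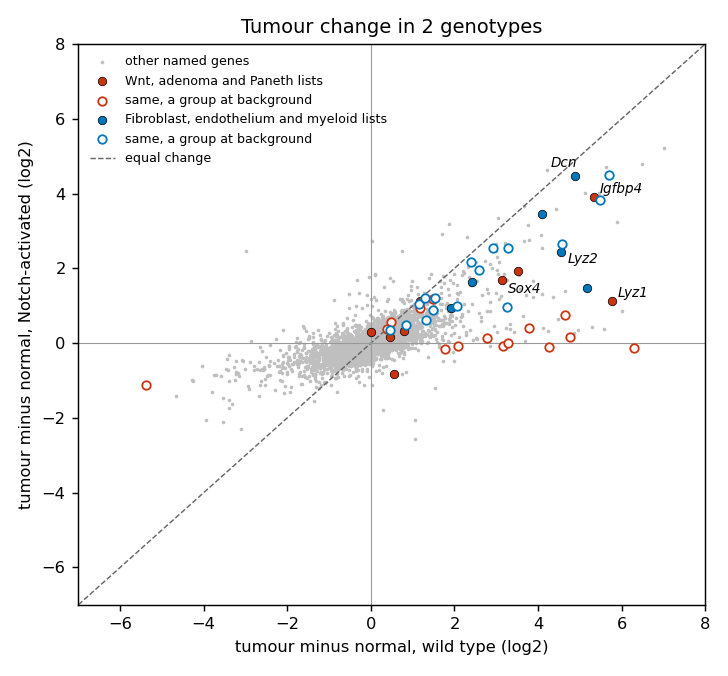
Tumour minus normal log2 difference of each named gene in wild type (horizontal) and Notch-activated mice (vertical), with members of 3 stromal and immune lists in blue, of the Wnt, adenoma and Paneth lists in red, equal change as a dashed line, and open circles for list members at background in a group, whose positions are not fixed. Dcn lies near that line (4.89 and 4.46), and Lyz2 (4.56 and 2.45), Sox4 (3.14 and 1.68) and Igfbp4 (5.33 and 3.91) lie below it.

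Averaged over the 3 genotypes, 7284 features were higher and 8023 lower in tumours, and with cyclic loess 7956 and 6895. Of these 15307 calls, 2166 had a direction that background leaves open. Il1rl1 rose by at least 5.85 on the log2 scale, Igfbp5 by at least 5.67, Serpina3n by at least 5.15, S100a9 by at least 4.95, Mgp by at least 4.93 and Dcn by 4.65 (SE 0.21). Mptx1 (-3.38 or lower), the goblet cell protein Clca1 (-3.27, SE 0.87) and Selenbp1 (-3.22, SE 0.16) were among the falls. Proliferation genes rose in 11 of 15 cases (adjusted p = 0.0106, and adjusted p = 0.516 with an estimated correlation). Mib1 rose by 0.25 (SE 0.06), and by 0.38 with cyclic loess. Apc fell by 0.17 (SE 0.06, adjusted p = 0.0241), a call that cyclic loess ended (-0.05, adjusted p = 0.452), as did leaving out wild type normal array 2, Notch-activated normal array 1, wild type tumour array 2, Notch-inactivated tumour array 1 or Notch-activated tumour array 1 (adjusted p = 0.0643, 0.0584, 0.0534, 0.0587 and 0.0577).

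In normal tissue, Notch-inactivated mice had higher Paneth cell genes than wild type mice. Defa5 was at background in wild type normal tissue and at 11.05 ± 1.01 in Notch-inactivated normal tissue (SD, n = 2), at least 39.2-fold higher, beside 11.74 ± 0.10 in wild type tumours. Defa25 rose by 5.80 (SE 0.65), Defa17 by 5.01 (SE 0.72), Lyz1 by 4.80 (SE 0.51), Defa21 at least 19.0-fold and Habp2 at least 4.09-fold. Of the 10 Paneth genes 7 rose (8 adjusted over the list alone) and 0 fell, with adjusted p = 3.63e-10, and adjusted p = 0.232 with an estimated correlation. None of the 10 Wnt targets was called (limma), and their list had a median of 0.08 and an adjusted p of 0.656. Of 8 goblet genes 0 rose and 0 fell, and their list was not called (camera without the features that background leaves open, adjusted p = 0.731). Other rises were those of Dlk1, a protein related to Notch ligands (4.65, SE 0.57), the secretoglobin Scgb2b26 (4.49, SE 0.44), Igfbp4 (1.63, SE 0.18) and the stem cell marker Prom1 (1.61, SE 0.15, or 0.78 with the mean over its probes). The interferon-induced Ifi27l2a fell by 3.38 (SE 0.46), the potassium channel Kcnq1 by 2.01 (SE 0.25) and the bicarbonate transporter Slc4a4 by 1.79 (SE 0.20).

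Some calls in Notch-inactivated normal tissue ended when 1 array was left out, in fits with fewer arrays. Slc1a1 (-1.74) was no longer called without wild type normal array 1 or 2 (-1.71 and -1.76, adjusted p = 0.0731 and 0.0758). Without wild type or Notch-inactivated normal array 2, Slc5a1 (-1.16) had -1.03 and -1.11 (adjusted p = 0.0727 and 0.0558) and Slc5a8 (-1.77) had -1.69 and -1.39 (0.0719 and 0.0615). Fam126a (-2.33) had -2.27, -2.38 and -1.71 without wild type normal array 1 or 2 or Notch-inactivated normal array 2 (adjusted p between 0.0955 and 0.111). For Anxa1, a gene of regenerating epithelium that rose by 1.04, the same arrays gave 1.09, 0.99 and 0.69 (0.0807, 0.118 and 0.0800). Among genes of the distal gut, Hoxd13 (-0.69) had -0.68, -0.70 and -0.52 without wild type normal array 1 or 2 or Notch-inactivated normal array 1 (0.0993, 0.0974 and 0.0885). Hoxb13 (-0.61, adjusted p = 0.0439) lost its call in 11 of 12 such fits, at -0.66 to -0.41, with adjusted p from 0.0517 to 0.186. Colonic markers fell in 2 of 11 cases with a list adjusted p of 0.0760, and enterocyte genes in 2 of 9 with 0.112. The myeloid, interferon and glycolysis lists were called (adjusted p = 0.0213, 0.0460 and 0.00705; adjusted p = 0.423, 0.539 and 0.423 with an estimated correlation), although none of their 9, 10 and 13 genes was called by limma over all features, and their medians were 0.40, -0.41 and 0.20. Without the features that background leaves open the interferon list had adjusted p = 0.0540. In this contrast 496 features were higher and 458 lower, 954 in all and 4076 at an unadjusted p under 0.05. A fit to only the arrays compared called 241, and array weights 489. The count was 547 and 366 without wild type normal array 1 and 2, and 504 without Notch-inactivated normal array 2.

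In normal tissue, Notch-activated mice had lower goblet cell and interferon response genes than wild type mice. Bcas1 fell by 5.76 (SE 0.34), Slc12a8 by 5.16 (SE 0.24) and Muc4 by 2.62 (SE 0.22), and 5 of 8 goblet genes fell (7 adjusted over the list alone) with adjusted p = 4.18e-11, and adjusted p = 0.139 with an estimated correlation. The resistin-like Retnlb had a difference of -5.09 (SE 1.58, adjusted p = 0.0860) and was not called. It was called at the same difference (adjusted p = 0.0404) when either Notch-inactivated normal array, which enters only the shared spread, was left out. H2-D1, a class I antigen-presenting molecule, was at background in wild type and at 10.96 ± 0.02 in Notch-activated normal tissue, at least 36.8-fold higher. A strain variant under the H2-D1 probe stays open for this and the other H2-D1 values. Krt13, a keratin of stratified epithelia, was at least 24.1-fold higher, Reg1 at least 5.46-fold and the protease Prss22 at least 5.13-fold, and Srd5a1 rose by 2.72 (SE 0.30) and Anxa1 by 1.44 (SE 0.20). The regenerative list, to which Anxa1 belongs, gained 2 of 6 genes (adjusted p = 0.00934, and adjusted p = 0.223 with an estimated correlation). It could not be tested without the features that background leaves open, as fewer than 5 genes remained.

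Interferon response genes fell in 6 of 10 cases in Notch-activated normal tissue (8 adjusted over the list alone; adjusted p = 3.22e-06, and adjusted p = 0.139 with an estimated correlation). Ifi27l2a fell by 4.71 (SE 0.46), Apol9a by 3.32 (SE 0.31) and Irf7 by 2.09 (SE 0.30), as did the kallikrein Klk1b27 by 3.16 (SE 0.37). Of the 10 antigen presentation genes 4 fell, among them H2-K1 by 1.15 (SE 0.15) and B2m by 1.05 (SE 0.20), 1 rose and 5 were not called (adjusted p = 0.00934, and adjusted p = 0.517 with an estimated correlation). Colonic markers fell in 2 of 11 cases, Car1 by 2.23, enterocyte genes in 2 of 9, Slc15a1 by 0.66, and tuft cell genes in 2 of 5, Trpm5 at least 2.33-fold and Dclk1 by 0.99. These 3 lists had adjusted p = 0.00121, 0.00934 and 0.0125, and adjusted p = 0.139, 0.156 and 0.231 with an estimated correlation. The tuft list could not be tested without the features that background leaves open, as fewer than 5 genes remained. Glycolysis genes rose in 2 of 13 cases (adjusted p = 0.00400, and adjusted p = 0.322 with an estimated correlation). Of 9 myeloid genes 3 rose, among them Cxcl1 (2.16) and C1qb (at least 2.11-fold), with adjusted p = 7.75e-04, and adjusted p = 0.139 with an estimated correlation.

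Leaving out 1 array also ended calls in Notch-activated normal tissue. B2m and the inflammasome gene Nlrc4 (2.67) were each lost without any 1 of the 4 arrays compared, with B2m between -1.10 and -1.01 and Nlrc4 between 2.59 and 2.75 (adjusted p from 0.0522 to 0.118). Igtp (-2.11) and Ifit3 (-1.19) were lost without either wild type normal array or Notch-activated normal array 2, at -2.29 to -1.73 and -1.34 to -0.93 (0.0559 to 0.169), and Trpm5 without wild type normal array 1 or either Notch-activated one (0.106 to 0.172). Dclk1 was lost in 9 of 12 fits (0.0561 to 0.224), at -0.63 without wild type normal array 1 and between -1.08 and -0.91 otherwise. Car1 was lost without wild type normal array 2 or Notch-activated normal array 1 (-1.86 and -1.90, adjusted p = 0.0662 and 0.0757), and Cxcl1 without wild type normal array 2 or Notch-activated normal array 2 (2.03 and 1.80, adjusted p = 0.0647 and 0.0893). Without that last array the calls of Mptx1 (-6.21 with it, -5.33 without), Psmb8 (-1.29 and -0.98) and C1qb also ended (0.0693, 0.0705 and 0.0752). The contrast called 844 features higher and 994 lower, 1838 in all. The count was 1134 and 1137 without wild type normal array 1 and 2, and 1003 and 987 without Notch-activated normal array 1 and 2.

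Between Notch-inactivated and wild type tumours few features could be told apart with 2 arrays per group. Of 23071 features 24 were higher and 21 lower, with 1017 at an unadjusted p under 0.05. The 7 named genes among them were Shoc2, a scaffold of the Ras pathway (1.31, SE 0.11, or 0.67 with the mean over its probes), the sulfhydryl oxidase Qsox1 (0.81, SE 0.09), the mitochondrial ribosomal gene Mrps10 (-0.66), Reg1 (-1.40, SE 0.16), A330102I10Rik (-1.87), Slc5a8 (-1.88) and the haemoglobin gene Hbb-b2 (-4.08, SE 0.53). The Hbb-b2 level was 10.17 ± 0.61 in wild type and 6.09 ± 0.21 in Notch-inactivated tumours, beside Hba-a1 at 12.74 ± 0.58 and 12.19 ± 0.07. Only the Shoc2 call held in every fit that left out 1 array. Wild type tumour array 1 ended that of Qsox1 (adjusted p = 0.0609), Notch-inactivated tumour array 2 those of Qsox1, Reg1, A330102I10Rik and Hbb-b2 (0.0798, 0.0544, 0.0787 and 0.0798), and Notch-inactivated tumour array 1 those of Reg1, A330102I10Rik and Hbb-b2 (0.0507, 0.104 and 0.0808). Wild type tumour array 2 ended those of A330102I10Rik and Hbb-b2 (0.0755 and 0.129). Slc5a8 and Mrps10 were lost in 7 and 10 of the 12 fits (0.0783 to 0.227 and 0.0607 to 0.230). The Paneth list was not called between these tumours, with a median of 0.18 and an adjusted p of 0.322, and on simulated data a shift of 0.5 of that list was found in 4 of 10 draws. Of the 19 lists, the colonic (median -0.43), stem cell (-0.38) and cholesterol (0.18) lists were called at adjusted p = 0.0434, 0.0434 and 0.0338, each at adjusted p = 0.713 with an estimated correlation and with 0 genes called by limma. The count of 45 became 23 without either Notch-activated normal array, 25 without wild type tumour array 2 and 18 without Notch-inactivated tumour array 2. In a fit to these 4 arrays alone it was 0, with 1291 features at an unadjusted p under 0.05.

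Notch-activated tumours had lower Paneth, Wnt target and adenoma genes than wild type tumours. Defa5 was at 5.40 ± 0.28 against 11.74 ± 0.10 in wild type tumours, at least 65.3-fold lower, and Defa25 fell by 6.26 (SE 0.65), Lyz1 by 6.13 (SE 0.51) and Habp2 by 3.19 (SE 0.21). In all, 8 of 10 Paneth genes fell (adjusted p = 3.63e-07, and adjusted p = 0.129 with an estimated correlation). Nkd1 fell by 3.83 (SE 0.14), Prox1 by 3.62 (SE 0.14), Sox4 by 1.68 (SE 0.21) and Wnt6 at least 3.06-fold, among 6 of 10 Wnt targets (adjusted p = 9.73e-04, and adjusted p = 0.129 with an estimated correlation). Adenoma genes fell in 7 of 9 cases (8 adjusted over the list alone, with 1 higher), with adjusted p = 9.37e-07, and adjusted p = 0.129 with an estimated correlation. Ptn (-5.11, SE 0.29), Slc9a3 (-5.02, SE 0.50) and the transcription factor Onecut2 (-2.69, SE 0.18) fell too, and Cadps, a protein of vesicle release, was at least 27.7-fold lower. Goblet genes fell in 2 of 8 cases, Bcas1 by 3.15 and Slc12a8 by 2.79 (adjusted p = 0.0270, and adjusted p = 0.504 with an estimated correlation).

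Myeloid and fibroblast genes were also lower in Notch-activated than in wild type tumours. Lyz2 fell by 1.23 (SE 0.22) and C1qa by 0.77 (SE 0.10) among 5 of 9 myeloid genes, and Mgp by 1.76 (SE 0.29) and Fbln1 by 1.34 (SE 0.21, or 0.76 with the mean over its probes) among 4 of 8 fibroblast genes (adjusted p = 4.89e-04 and 0.00401, and adjusted p = 0.129 and 0.272 with an estimated correlation). Of 5 endothelial genes 0 were called by limma, with a median of -0.12 and a list adjusted p of 0.324. Enterocyte genes rose in 4 of 9 cases, Slc5a1 by 1.38 and Mep1b by 0.93, with adjusted p = 0.00845, and adjusted p = 0.136 with an estimated correlation. Mep1b lost its call without wild type tumour array 1 or Notch-activated tumour array 1 (adjusted p = 0.0529 and 0.0562). Cholesterol genes rose in 3 of 11 (Lss 0.96) and glycolysis genes in 4 of 13 (adjusted p = 0.00908 and 0.0355, and adjusted p = 0.504 for both with an estimated correlation). Without the features that background leaves open the glycolysis list had adjusted p = 0.0577. H2-D1 (5.08, SE 0.19), Krt13 (3.25, SE 0.29), Slc1a1 (2.90, SE 0.31) and the glucuronidation genes Ugt1a7c (2.94), Ugt1a6a (2.89) and Ugt1a6b (2.88, or 1.61 with the mean over its probes), which share exons and so are not separate evidence, were among the largest rises. The contrast called 2483 features higher and 2371 lower, 4854 in all, with cyclic loess 2074 and 2687, and 2946 and 2955 without wild type tumour array 1 and Notch-activated tumour array 1.

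**Figure D3:**
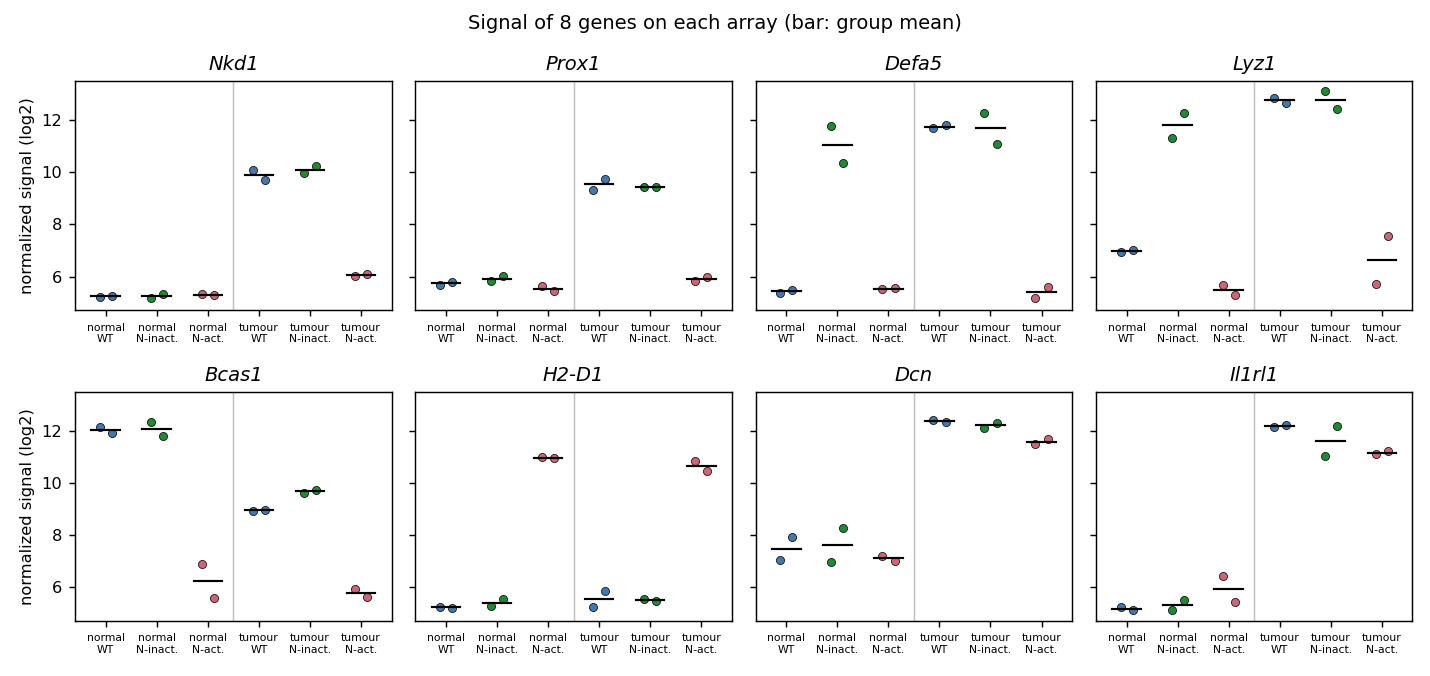
Normalized log2 signal of 8 genes on each array (points, 2 per group) with the group mean (bar), for normal and tumour tissue of wild type (WT), Notch-inactivated (N-inact.) and Notch-activated (N-act.) mice. Defa5 is high in Notch-inactivated normal tissue (11.05) and in wild type tumours (11.74) and low in Notch-activated tumours (5.40), where Dcn remains high (11.57).

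The Notch-activated and Notch-inactivated genotypes were also set against each other, and differed in Paneth and goblet genes in both tissues and in Wnt, adenoma and other lists in tumours. In normal tissue 9 of 10 Paneth genes fell (Defa25 -7.21, SE 0.65, and Lyz1 -6.29, SE 0.51) and 5 of 8 goblet genes (Slc12a8 -5.83, Bcas1 -5.80, Muc4 -3.43). These lists had adjusted p = 8.30e-11 and 1.79e-10, and adjusted p = 0.102 for both with an estimated correlation. Tuft cell and interferon genes fell in 1 of 5 and 1 of 10 cases (adjusted p = 0.00491 and 0.00241, and adjusted p = 0.313 and 0.448 with an estimated correlation). The tuft list could not be tested here without the features that background leaves open, as fewer than 5 genes remained. H2-D1 was at least 37.6-fold and Reg1 at least 5.57-fold higher. In tumours Defa5 was at least 62.4-fold and Cadps at least 31.8-fold lower, and Defa25 fell by 6.31, Lyz1 by 6.13, Ptn by 5.24, Nkd1 by 4.03 and Prox1 by 3.51. H2-D1 was at least 32.9-fold higher, and Slc5a8 (4.46), Ugt1a6b (3.91, or 2.12 with the mean over its probes) and Aqp4 (3.67) rose. The Paneth (8 of 10 fell), adenoma (6 of 9) and Wnt lists (6 of 10 fell, 1 rose) had adjusted p = 1.60e-07, 1.43e-05 and 3.58e-04 in tumours, and adjusted p = 0.109 for each with an estimated correlation. Myeloid (5 of 9), fibroblast (3 of 8) and goblet genes (3 of 8) fell there as well, with adjusted p = 3.92e-04, 0.00923 and 0.00980, and adjusted p = 0.109, 0.345 and 0.358 with an estimated correlation. Enterocyte (3 of 9) and glycolysis genes (5 of 13) rose, with adjusted p = 0.00923 and 0.00784, and adjusted p = 0.142 and 0.358 with an estimated correlation. The contrast called 2097 features in normal tissue, or 960 without Notch-activated normal array 2 and 1346 in a fit to only the arrays compared, and 4926 in tumours, or 2878 and 3045 without Notch-inactivated tumour array 2 and Notch-activated tumour array 1.

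The effect of the Notch-inactivated genotype differed between tumour and normal tissue for 161 features, 60 with a higher and 101 with a lower value in tumours, and for 65 (14 and 51) in a fit to only the arrays compared. Other differences between the mice were not separated from the genotype. For 13 of the 161 features background leaves the direction open. Paneth genes were among the others: Defa5 had a difference of -5.36 or lower, and the list, with 3 of 10 members called lower (7 adjusted over the list alone), had adjusted p = 2.13e-09, and adjusted p = 0.275 with an estimated correlation. Glycolysis, antigen presentation, interferon and regenerative lists had adjusted p = 3.35e-04, 0.0240, 0.0279 and 0.0293 without any member called by limma, and adjusted p = 0.560, 0.673, 0.613 and 0.560 with an estimated correlation. The regenerative list could not be tested without the features that background leaves open, as fewer than 5 genes remained. Krt13 (-3.02 or lower), the mast cell protease Cma1 (-2.81, SE 0.36), Abi3 (1.90, SE 0.16), Sned1 (1.80, SE 0.22) and Shoc2 (1.37, SE 0.15, or 0.73 with the mean over its probes) kept their calls when any 1 array was left out. Defa25 (-5.76), Lyz1 (-4.79), Habp2 (-1.71 or lower) and Slc4a4 (1.87) lost theirs in 7, 8, 7 and 6 of 12 such fits, with adjusted p up to 0.0929, 0.0763, 0.0881 and 0.0766. Hbb-b2 (-4.32), Hyi (1.96) and Dgkg (0.86 or higher) lost theirs in 10, 10 and 11, with adjusted p up to 0.128, 0.151 and 0.140. Dgkg also lost its call with cyclic loess (adjusted p = 0.0625). The count was 61, 57 and 57 without wild type normal array 2 and Notch-activated normal arrays 1 and 2. It was 96 and 69 without wild type tumour arrays 1 and 2, and 90 and 76 without Notch-inactivated tumour arrays 1 and 2.

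The effect of Notch activation differed between the tissues for 2753 features, 1500 with a higher and 1253 with a lower value in tumours. For 451 of them background leaves the direction open, among them Nkd1, Prox1, Wnt6, Defa5, Ptn, Mgp, Cadps and Onecut2, which lay at background in Notch-activated normal tissue and could not be seen to fall there. Among differences not left open, Sox4 (-1.45, SE 0.29), Igfbp4 (-1.42, SE 0.25), Mt4 (-5.20), Lyz1 (-4.63, SE 0.72), Defa25 (-4.86) and Habp2 (-3.14 or lower) were lowered in tumours in excess of normal tissue. Lyz1 and Defa25 exceeded background on 1 of the 2 arrays of Notch-activated normal tissue. Goblet and enterocyte genes had the opposite difference, Bcas1 2.61, Slc12a8 2.37, Slc5a1 1.61 and Mep1b 1.53, and so did Ifi27l2a (5.45), Slc5a8 (3.43), Selenbp1 (3.25), Apol9a (3.09) and Mettl7b (3.03). The adenoma (5 of 9 lower), myeloid (5 of 9 lower, such as C1qb at -2.13 or lower and Lyz2 at -2.11) and enterocyte lists (4 of 9 higher) had adjusted p = 2.53e-07, 1.72e-06 and 3.75e-05, and each had adjusted p = 0.0450 with an estimated correlation. The Wnt (4 of 10 lower), Paneth (5 of 10 lower) and goblet lists (5 of 8 higher) had adjusted p = 2.33e-04, 3.75e-05 and 3.75e-05, and adjusted p = 0.0997, 0.151 and 0.151 with an estimated correlation. Without the features that background leaves open, the adenoma, Wnt, Paneth and fibroblast lists held fewer than 5 genes and could not be tested. The myeloid (5 of 6), enterocyte (4 of 7) and goblet lists (5 of 7) then had adjusted p = 7.72e-06, 4.57e-04 and 2.19e-04, and adjusted p = 0.0433, 0.124 and 0.169 with an estimated correlation. Interferon (3 of 10), antigen presentation (3 of 10) and colonic genes (2 of 11) were higher by the same measure and fibroblast genes (1 of 8) lower, with adjusted p = 4.33e-04, 0.00543, 0.00158 and 0.00764, and adjusted p = 0.189, 0.439, 0.129 and 0.257 with an estimated correlation. Gsdmc3 (3.30) lost its call without either wild type normal array, Notch-activated normal array 2, wild type tumour array 1 or either Notch-activated tumour array (adjusted p = 0.0523 to 0.0850). The count was 1750 and 1719 without wild type and Notch-activated normal array 2, and 1662 and 1592 without wild type and Notch-activated tumour array 1.

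The effects of both Notch genotypes were set side by side within each tissue, where they share the wild type arrays. In normal tissue r across features was 0.293, beside 0.500 simulated for unchanged groups, and the covariance 0.0471 beside 0.0136 simulated, a difference of 0.0335. There 176 features were higher in both (18.1 from independent lists) and 151 lower in both (19.7), while 21 and 56 were called in opposite directions. In tumours r was 0.00866 beside 0.499 simulated and the covariance 9.68e-04 beside 0.0137, a difference of -0.0127, with 5 features higher in both (2.58) and 14 lower in both (2.16), while 4 and 8 were called in opposite directions. Part of these overlaps may come from the shared wild type arrays, which are too few to be split. The Notch-activated effect in normal tissue and in tumours, which share no arrays, had r = 0.311. Of the calls 412 were higher in both tissues (90.8 from independent lists, Fisher's exact p = 2.18e-179, a value that takes features as independent) and 249 were lower in both (102; p = 1.83e-42), with 55 and 78 called in opposite directions.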

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

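The tests of explanations below were all chosen after the results had been seen, except the count over other splits of the samples, which was set beforehand. Genes are not independent replicates, so tests over genes describe these 12 arrays.

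Wnt, adenoma and Paneth genes, as lists, were lower in Notch-activated than in wild type tumours (list adjusted p = 9.73e-04, 9.37e-07 and 3.63e-07, and adjusted p = 0.129 for each with an estimated correlation). Normal tissue mixed into the tumour samples would leave 1 tumour share for all genes, but the median share was 56.2% over 21 stromal, endothelial and myeloid genes and 8.74% over 20 Wnt, adenoma and Paneth genes (permutation p = 3e-05, two-sided). Within the second set the Paneth shares ran from -4.25% (Defa29) to 14.5% (Cd24a). The Wnt and adenoma shares ran from -2.09% (Wnt6) to 219% (Cd44), with Ccnd1 at 169% and Nkd2 at 101%. Cldn2, Ascl2 and Igfbp4 stood at 31.8%, 33.0% and 37.2%, beside C1qb at 31.2% and Lyz2 at 37.7% in the first set. The permutation test pooled the Paneth genes, which mark 1 cell type, with the Wnt and adenoma genes. Every Paneth share lay below the lowest share of the first set (23.7%, Fbln1). For the Paneth genes these shares argue against admixture alone, although these genes were not tested apart. For the Wnt and adenoma genes admixture alone stays open, because their shares overlapped those of the first set. A part played by admixture stays open for all lists, since the stromal median lay below the wild type level too. A wrong genotype label is argued against by eGFP, at least 9.50 on every Notch-activated array and at most 5.48 on the others. An effect of Notch activation on the epithelium of the tumours is the hypothesis that the design names. A difference in tumour stage, size or gut segment may also contribute and was not tested, and the labels do not name the segment. Onecut2, of the duodenal and jejunal list, was lower in Notch-activated than in wild type tumours. Of the colonic markers 1 of 10 rose and 0 fell there, and their list was not called (camera without the features that background leaves open, adjusted p = 0.318).

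Paneth genes were higher in normal tissue of Notch-inactivated mice, with a list adjusted p of 3.63e-10, and adjusted p = 0.232 with an estimated correlation. Adenoma tissue in those samples would bring Wnt and adenoma genes along, but the median implied adenoma share was 88.6% for 8 Paneth genes and 0.559% for 12 Wnt and adenoma genes (exact permutation p = 0.000445, two-sided). Paneth shares ran from 40.0% (Habp2) to 328% (Defa3), and Wnt and adenoma shares from -79.7% (Ascl2) to 20.1% (Ccnd1). The adenoma gene Igfbp4, which rose in these samples, stood at 5.33%. Small intestine, where Paneth cells are common, would raise enterocyte genes, and their mean over 9 genes moved by -0.33 (95% interval -0.53 to -0.12). Slc5a1 went from 10.09 to 8.93 and Apoa4 from 6.94 to 6.12. Apoc2, Apoa1 and Slc2a5 went the other way, from 6.43 to 7.01, 6.84 to 6.99 and 5.80 to 5.91. A more proximal piece of large intestine stays open, because Hoxd13 differed by -0.69 and Hoxb13 by -0.61, calls that were lost in 3 and 11 of the 12 fits without 1 array. A shift of secretory cells towards Paneth cells without Notch signalling could give the same Paneth values, and the labels do not name the gut segment that would decide it. Goblet genes, another secretory type, were not seen to change: 0 of 8 rose and 0 fell. Their list was not called (camera without the features that background leaves open, adjusted p = 0.731), which does not show that they stayed the same.

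A set of 49 named genes, 34 higher and 15 lower, was called and changed at least 2-fold in the same direction by Notch activation in normal tissue and in tumours. Of these, 16 had another member within 10 tested genes on the chromosome, against 8.12 on average in 10000 random sets (permutation p = 0.0237, one-sided). Segments of donor strain genome carried along with the transgene may therefore account for some of the set, as may groups of related genes that lie together. For H2-D1, a general rise of class I antigen presentation is argued against by H2-K1, which differed by -1.15 in normal tissue, and a strain variant under the H2-D1 probe stays open. A response to Notch in both tissues remains a hypothesis for the rest.

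For the tumour difference averaged over genotypes, chance can be excluded as the source of its count if the 12 arrays are separate samples. If the 2 arrays of a group are repeats of 1 sample, the splits of the groups are too few to exclude it. Of 100 splits drawn from the 108 that keep the genotypes balanced, 1, the real one, reached its count of 14455 in an additive fit, while the highest other split gave 6478 and the median of the others was 0.

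The effect of the Notch-inactivated genotype differed between tumour and normal tissue, by a test of the difference itself, for 12 of the genes named as measured and for 4 as a bound (limma, adjusted p from 0.00177 for Abi3 to 0.0463 for Hyi). The difference was positive for Hyi (1.96), Abi3 (1.90), Slc4a4 (1.87), Sned1 (1.80), Shoc2 (1.37, or 0.73 with the mean over its probes) and Dgkg (0.86 or higher). It was negative for Defa25 (-5.76), Defa5 (-5.36 or lower), Lyz1 (-4.79), Hbb-b2 (-4.32), Krt13 (-3.02 or lower), Cma1 (-2.81), Habp2 (-1.71 or lower), Igfbp4 (-1.65), Prom1 (-1.36) and Mrps10 (-1.02). Reg1 lay at background in both normal groups, which leaves its difference open. Shoc2 and Hyi also belong to the set of 49 genes that Notch activation shifted alike. Whether the mice differed in strain background was not tested for any of these genes. Calls were lost in 11 of 12 fits without 1 array for Dgkg (adjusted p up to 0.140), 10 for Hyi and Hbb-b2 (0.151 and 0.128), 8 for Lyz1 (0.0763) and 7 for Defa25 and Habp2 (0.0929 and 0.0881). For Igfbp4 and Slc4a4 the number was 6 (0.0839 and 0.0766), for Prom1 5 (0.0839) and for Mrps10 2 (0.0597, without wild type tumour array 1 or Notch-inactivated tumour array 2). The mean over its probes also ended the call of Prom1 (-0.66, adjusted p = 0.0909), and cyclic loess that of Dgkg (adjusted p = 0.0625).

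The effect of the Notch-activated genotype differed between the tissues by the same test for 29 of the genes named as measured and for 5 as a bound (limma, adjusted p from 3.18e-04 for Habp2 to 0.0456 for Car1). Positive differences belonged to Ifi27l2a (5.45), Slc5a8 (3.43), Gsdmc3 (3.30), Selenbp1 (3.25), Apol9a (3.09), Mettl7b (3.03), Slc1a1 (2.93), Klk1b27 (2.92), Bcas1 (2.61), Muc4 (2.46), Ugt1a6b (2.40, or 1.33 with the mean over its probes), Ugt1a7c (2.38), Slc12a8 (2.37), Ugt1a6a (2.27), Irf7 (2.09), Car1 (2.04), Slc5a1 (1.61), Psmb8 (1.60), Mep1b (1.53), Slc15a1 (0.84) and H2-K1 (0.77). Negative ones belonged to Mt4 (-5.20), Defa25 (-4.86), Lyz1 (-4.63), Cxcl1 (-3.72), Slc9a3 (-3.62), Habp2 (-3.14 or lower), Reg1 (-2.32 or lower), C1qb (-2.13 or lower), Lyz2 (-2.11), Sox4 (-1.45), Igfbp4 (-1.42), Krt13 (-1.33 or lower) and C1qa (-0.92 or lower). The differences of Defa5, Ptn, Cadps, Nkd1, Prox1, Onecut2, Wnt6 and Mgp are left open by background in Notch-activated normal tissue. Calls were lost in 9 of 12 fits without 1 array for H2-K1 (adjusted p up to 0.151), 8 for Car1 (0.152), 6 for Gsdmc3 (0.0850), 5 for Krt13 (0.113) and 1 for Irf7 (0.0518, without Notch-activated normal array 2). Without a filter on dim probes those of Car1 and H2-K1 also ended (0.0594 and 0.0542).

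Among probes for sequences foreign to the mouse, which enter none of the comparisons, the lowest signal on a Notch-activated array was 9.50 for eGFP and 7.39 for IRES, above the highest on the other 8 arrays (5.48 and 5.57).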

How the results depend on the processing

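Cyclic loess, a stricter filter on dim probes, the crossed pairing and list tests without the features left open by background were chosen after seeing the data. Not run were normexp with a fixed offset, no background correction, the BeadChip as a block and cyclic loess after background correction, because the signal table could not be tied to samples, and the authors' values were the ones reported.

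Gene results were refitted without 1 array, without a filter, with the stricter filter, with the mean over probes and with cyclic loess. Array weights, trend and robust settings, the replicate block and fits to only the arrays compared were not run gene by gene. Many fits without 1 array left the compared group means unchanged, so no direction could change in them. Of 255 gene results, 0 changed direction in 4080 refits by limma, 217 refits ended a call, all but 6 of them without 1 array, and 3 made one. The other ended calls were those of Car1 (2.04, adjusted p = 0.0594) and H2-K1 (0.77, 0.0542) in the tissue difference of the Notch-activated effect with no filter, where more features are tested, and Prom1 (-0.66, 0.0909) in that of the Notch-inactivated effect with the mean over probes. With cyclic loess they were Mib1 (0.35, 0.0741), Apc (-0.05, 0.452) and Dgkg (0.0625), and the cause was not tested.

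A further requirement of at least a 2-fold change left 3030, 2832, 740 and 1996 features for tumour against normal tissue in wild type, Notch-inactivated and Notch-activated mice and on average. It left 311 and 636 for Notch-inactivated and Notch-activated against wild type normal tissue, 29 and 1334 for tumours, 649 and 1446 for the Notch genotypes against each other in normal tissue and tumours, and 1343 for the tissue difference of the Notch-activated effect. It moved the share of higher calls to 81.1% from 48.7% for Notch-activated tumours against normal tissue, to 58.6% from 47.6% on average, to 65.6% from 52.0% for Notch-inactivated normal tissue and to 33.1% from 49.0% between the Notch genotypes in normal tissue. Fits to only the arrays compared gave 241 calls for Notch-inactivated normal tissue (62.7% higher), 0 for Notch-inactivated tumours (limma, 1291 at an unadjusted p under 0.05), 1346 between the Notch genotypes in normal tissue and 65 for the tissue difference of the Notch-inactivated effect (21.5% higher against 37.3%), with fewer arrays to estimate the spread. Array weights gave 489 for Notch-inactivated normal tissue. The weights came out equal for the 2 arrays of each group, so they weighed whole groups and could not mark a poor array. With an estimated correlation 3 list calls were left of 94. Without the features that background leaves open, camera called 88 lists, 83 of them also called with all features. The interferon list in Notch-inactivated normal tissue (adjusted p = 0.0540) and the glycolysis list in Notch-activated tumours (0.0577) were not called. The other lost calls had fewer than 5 genes left and were untested: those named above and the Paneth list for tumours averaged over genotypes. Newly called were goblet (higher) and glycolysis genes (lower) in Notch-inactivated against wild type tumours, and colonic genes (higher) in Notch-activated against Notch-inactivated tumours. So were myeloid and fibroblast genes (lower) in the tissue difference of the Notch-inactivated effect. None of these held with an estimated correlation. The balance of higher and lower calls depended on the scaling: cyclic loess gave 6104 and 4853 for wild type, 6154 and 5174 for Notch-inactivated and 3134 and 2220 for Notch-activated tumours against normal tissue, 7956 and 6895 on average, 20 and 21 for Notch-inactivated and 2074 and 2687 for Notch-activated against wild type tumours. The stricter filter turned it too, to 5171 and 4770, 5449 and 4573, 2612 and 2095, and 6658 and 5926 for tumours against normal tissue in the same order.

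The replicate block moved no count by over 1.5 times (45 for Notch-inactivated tumours, 124 for the tissue difference of the Notch-inactivated effect, 10730 for wild type tumours against normal tissue within genotype), and the numbers were not taken to pair samples. A crossed pairing gave 0 calls for Notch-inactivated tumours (limma, 1726 at an unadjusted p under 0.05) and 4704 for Notch-activated tumours.

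Leaving out 1 array at a time assumes that the lone array of a group varies like the others. Counts then ranged from 8519 to 11645 for tumour against normal tissue in wild type, 8577 to 11586 in Notch-inactivated and 2656 to 6102 in Notch-activated mice, and 14309 to 14993 on average. They ranged from 366 to 917 and 987 to 2024 for Notch-inactivated and Notch-activated against wild type normal tissue, 18 to 49 and 2946 to 5039 for tumours, 960 to 2091 and 2878 to 5079 between the Notch genotypes, and 57 to 169 and 1592 to 2898 for the tissue differences. List calls ranged from 85 to 101. Signals near background limit what can be said of dim genes, for which only bounds are given.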

Other observations

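The following was looked at after the data had been seen. Immunoglobulin variable region probes, recognised by their probe identifiers and not part of any gene list, mark B lineage cells. Of 289 such probes 163 were kept. Their median signal lay between 5.40 and 5.51 on the normal arrays and between 5.82 and 6.46 on the tumour arrays. Called higher in tumours were 107 in wild type, 78 in Notch-inactivated and 67 in Notch-activated mice, and called lower were 6, 7 and 5. In Notch-activated against wild type tumours 1 was higher and 23 were lower, and for Notch-inactivated against wild type tumours 0 and 6. These probes share sequence, so they are not separate evidence, and alternatives were not run for them.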
